A study of Mus musculus with 2 samples.

How the data were processed

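Single-cell RNA sequencing was performed on tumour cells of mice in which Math1-Cre switches on SmoM2, an activated form of the SHH receptor component Smoothened, in the granule neuron lineage of the cerebellum. 1 library came from tumour tissue after standard proton irradiation and 1 from tumour tissue after FLASH proton irradiation, which delivers the dose at an ultra-high rate. The sample labels give a dose of 5 Gy and the series design gives 10 Gy, and this conflict could not be settled from the files. The time after irradiation and the number of mice behind each library are not given in the sources used here. Mice were perfused with PBS and EDTA, the tissue was digested with collagenase-II and DNase, and the suspension passed a mesh with pores of 100 μm before V3 libraries of 10x Genomics were made.

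The deposited matrices held raw UMI counts, which the authors made with Cell Ranger 6.1.2 per the file headers and with the mm10 genome per the submitters' notes. The annotation release used by the authors is not given in the sources used here. The values were checked to be whole numbers, and the barcodes listed had at least 500 UMIs each. Both files listed the same 31055 features, among them the transgenes Cre and SmoM2EYFP, and 35 symbols were listed more than once. Coordinates were taken from GENCODE release M21 by gene ID, which matched 30934 of the features. The standard library held 12867 barcodes with 55532202 UMIs and the FLASH library held 14269 barcodes with 63178900 UMIs.

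Barcodes were kept with at least 500 detected genes and at most 10% mitochondrial UMIs. In the standard library 2819 barcodes had fewer genes and 1587 had more mitochondrial UMIs, and in the FLASH library these were 2352 and 1551. Scrublet, run per library in scanpy 1.11.5, gave an automatic cutoff that did not work, since it marked 1 of 8461 cells and 0 of 10366 cells. The fallback set beforehand for a cutoff that marks under 0.5% was used instead: the cells with the highest scores were removed at a rate of 0.8% per 1000 cells, which took out 573 cells (6.77%) and 860 cells (8.30%). The standard library kept 7888 cells with 45243188 UMIs and the FLASH library kept 9506 cells with 51532760 UMIs. Xist, the long RNA of the inactive X chromosome, had 82033 UMIs in the standard library and 99868 in the FLASH library, while the Y-linked gene Ddx3y had 0 in both, so both libraries came from females.

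Cells of both libraries were clustered together without batch integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes without ribosomal, mitochondrial and sex-linked genes were taken, and 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 with leidenalg 0.10.2 and igraph 0.11.9. Clusters were named from fixed marker lists of cell types, with the suffix -like used because no label names a cell type. A cluster needed a mean marker log2 ratio of at least 1.5 for a type outside the granule neuron lineage, and at least 3 markers with a log2 ratio of at least 1.0 over the other clusters after adding 20 CPM. A cluster with a median depth below 1/3 of its library's median and none of its type's markers among its 10 leading genes stayed unnamed. Leukocyte clusters were split again into 9 clusters. These naming cutoffs and the second split were set after seeing the data. The result was 30 clusters. Granule neuron progenitor-like and differentiating granule neuron-like clusters together are called tumour-lineage cells.

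For each class with at least 50 cells in each library, UMIs were summed per library and expressed as counts per 1000000 of that sum (CPM). The log2 ratio of FLASH over standard was taken after adding 0.5 count to each sum. Intervals are at 95% confidence: exact Clopper-Pearson for shares of cells, exact Poisson for CPM, and exact conditional binomial for ratios. They cover counting error only, which does not include the spread between animals or preparations. For expression values it does not include the spread between cells either. With 1 library per group no test between groups was possible, cells were not used as replicates, and every difference has no replicate check. Where a count was 0, a floor of 3 counts was used.

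The comparisons, the gene lists, the rule for naming genes and all alternatives except those marked as added later were fixed before the data were examined. Genes with at least 100 UMIs over both libraries and at least 50 CPM in 1 of them were ranked by log2 ratio, and the 10 highest and 10 lowest were named in tumour-lineage cells and in macrophage-, microglia- and monocyte-like cells together (the 5 highest and 5 lowest in other classes). Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes and models without a gene name were left out of this ranking. Of the genes this rule selected, 1 is not reported here. From each gene list the 4 members with the largest absolute ratio were named too. The lists covered SHH targets, p53 targets, S phase, G2 and M phase, granule neuron differentiation, DNA damage repair, apoptosis, NRF2 and antioxidant genes, interferon-stimulated genes, MHC class I and II, pro-inflammatory and alternative macrophage genes, PPAR gamma and lipid handling, lipid oxidation and ROS production, cholesterol synthesis, phagocytosis and lysosome, homeostatic microglia, hypoxia and glycolysis, immediate early and heat shock genes that tissue digestion raises, haemoglobin, and free RNA from tumour and from myeloid cells. Lists for T cells and endothelial cells were not evaluated, since these classes had 20 and 33 cells in the standard library. A list was described by the median log2 ratio of its members with at least 50 UMIs, by how many members differed by at least 1.5 times, and by its percentile among 10000 random lists matched on expression, each member drawn from the 200 nearest genes, as a description of these libraries. Ranges of list medians came from 2000 Poisson resamples of the counts.

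Shares of cells with a UMI were computed on all cells and after each cell was thinned to 2000 UMIs, with shallower cells left out. Alternatives changed the gene minimum, the mitochondrial limit, doublet removal, clustering resolution, joint clustering, scaling, weighting of cells, depth, list minimum and added count. Added after seeing the data were leukocyte clusters without the second split, clusters held to the same mix in both libraries, sums without the 5 cells with most UMIs of each gene where at least 10 UMIs were left, and the class shares without a cluster rich in nuclear RNA. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

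The ratio step was tested on simulated data with known changes at the depth of each class. Counts were drawn as Poisson sums per class, without single cells. Interval coverage near 95% was thus built in, and UMIs concentrated in few cells were not covered. In tumour-lineage cells 67 genes set to differ 1.5-fold all came out in the right direction, and among 2992 genes without a set change 0% passed 1.5-fold and the interval held the true value for 95.2%. In the macrophage-, microglia- and monocyte-like class these values were 67 of 67, 0.54% of 2409 genes and 94.6%. Of 200 lists of 20 genes without a set change, 3% fell outside the central 95% of random lists in the tumour-lineage class and 5% in the myeloid class, and a list raised 1.5-fold had a median of 0.58 and of 0.54.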

Results

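Single-cell expression was measured in tumour tissue of Math1-Cre;SmoM2 mice, a model of SHH medulloblastoma, after standard proton irradiation (1 library) and after FLASH proton irradiation (1 library). The standard library gave 7888 kept cells with a median of 5571 UMIs and the FLASH library gave 9506 kept cells with a median of 5212 UMIs. The median share of mitochondrial UMIs was 3.60% and 3.68%. The comparison of the libraries addresses how the tumour cells and the cells around them differed between these modes of dose delivery. There are no replicates, so each difference below describes these 2 libraries, and all intervals cover counting error only. Log2 ratios are FLASH over standard.

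Granule neuron lineage cells made up 80.5% of the standard library and 81.2% of the FLASH library. Within them, granule neuron progenitor-like cells, which carry the SHH program and divide, were 46.9% (95% interval 45.8 to 48.0) of all kept cells after standard and 50.5% (49.5 to 51.5) after FLASH. Differentiating granule neuron-like cells, named by markers of neurons that have begun to leave the cycle, were 33.6% (32.6 to 34.7) and 30.7% (29.8 to 31.6). The proliferation marker Mki67 is still among the leading genes of their cluster of 548 standard and 389 FLASH cells. Macrophage-, microglia- and monocyte-like cells together were 2.48% and 2.36%, a log2 ratio of -0.077 (-0.36 to 0.21). Within this myeloid group, macrophage-like cells took 59.7% and 61.2%, microglia-like cells 29.1% (22.8 to 36.0) and 18.3% (13.5 to 24.0), and monocyte-like cells 11.2% (7.17 to 16.5) and 20.5% (15.4 to 26.4).

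Oligodendrocyte lineage cells made up 1.52% and 1.76% of cells, endothelial-like cells 0.418% and 0.526%, and erythroid-like cells 0.355% and 0.368%. T cell-like cells were 20 (0.254%) and 24 (0.252%), dendritic cell-like cells 16 and 19, neutrophil-like cells 14 and 21, astrocyte-like cells 6 and 16, and fibroblast-like cells 7 and 8. Unnamed clusters, mostly of low depth, held 13.9% and 12.9%. The log2 ratio of the progenitor-like share, 0.11, lay between 0.022 and 0.22 over 10 alternatives. That of the oligodendrocyte lineage share, 0.21, turned to -0.44 with at most 5% mitochondrial UMIs. Collagenase digestion, the mesh and cell survival in suspension can set these shares. The lower share of differentiating cells (log2 ratio -0.13) rested in part on a nuclear-RNA-rich cluster of 548 standard and 389 FLASH cells, without which its log2 ratio was -0.048. It also depended on the choice of cells, with -0.0014 with doublets kept, -0.0018 with at least 1000 genes and -0.034 with at most 5% mitochondrial UMIs. It turned to 0.093 with a minimum of 200 genes and was -0.30 when each library was clustered by itself. With doublets kept, the progenitor-like share was at 0.022. The microglia-like share rested on 57 and 41 cells, and its log2 ratio of -0.74 turned to 0.47 when each library was clustered by itself. The monocyte-like share rested on 22 and 46 cells, and its log2 ratio of 0.79 lay between 0.34 and 0.83 in 6 of the 10 alternatives. In the others the monocyte-like class was not found in both libraries.

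**Figure D1:**
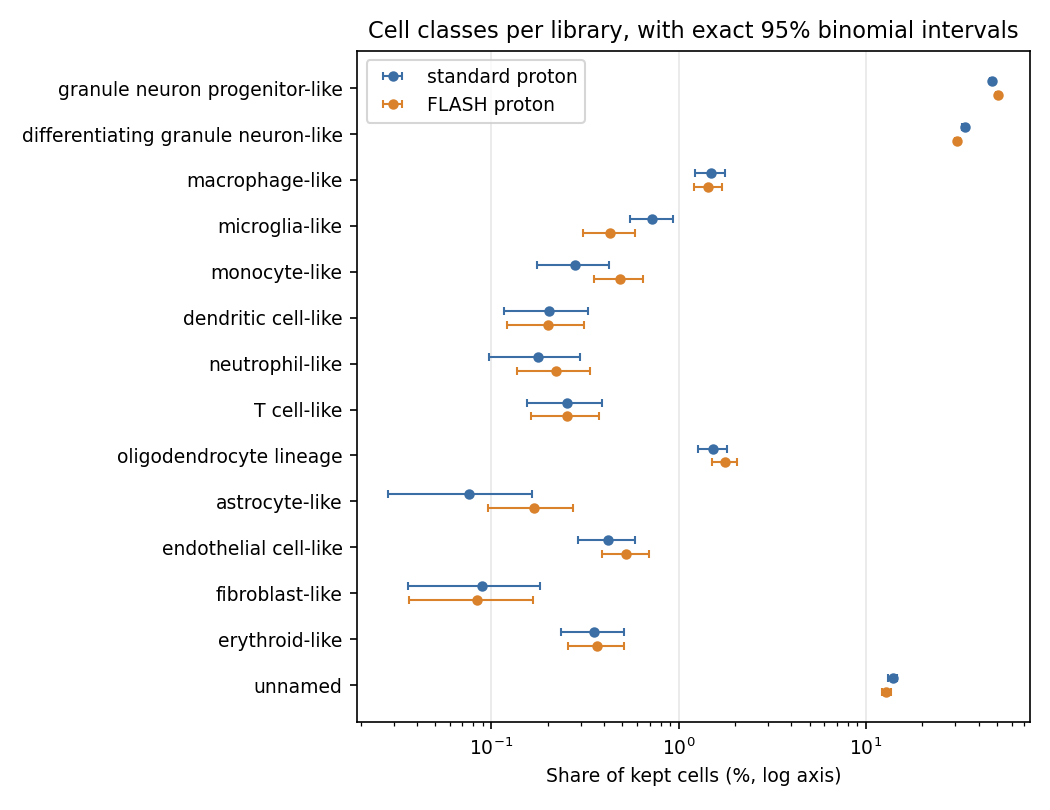
Share of kept cells in each class (%, log axis) in the standard and the FLASH proton library, as points with exact 95% binomial intervals. Progenitor-like cells lie at 46.9% and 50.5%, and microglia-like and monocyte-like cells part in opposite directions.

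In tumour-lineage cells (6351 standard, 7718 FLASH), 99.9% of 3192 genes with enough counts lay within 1.5 times of each other. Eif4ebp1, which encodes a repressor of cap-dependent translation, had 64.1 CPM after standard and 89.6 CPM after FLASH (log2 ratio 0.48, 0.41 to 0.55). Mthfd2, a mitochondrial folate enzyme, had 53.9 and 74.7 CPM (0.47, 0.39 to 0.55), and Asns, which makes asparagine, had 76.0 and 93.3 CPM (0.30). Psat1, an enzyme of serine synthesis, was higher by 0.29, the arginine and lysine carrier Slc7a1 by 0.31, Mat2a, which makes S-adenosylmethionine, by 0.28, and the stress-responsive transcription factor Atf5 by 0.28.

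Mbp, which encodes myelin basic protein, had the highest ratio in tumour-lineage cells, with 96.3 CPM (93.3 to 99.4) after standard and 137 CPM (134 to 140) after FLASH. It is a transcript of oligodendrocytes. Like Lars2 below, Mbp is also among the leading genes of unnamed clusters of low depth, which were left out of this class. In macrophage-, microglia- and monocyte-like cells Mbp stood at 75.5 and 102 CPM (0.43, 0.087 to 0.77), and in oligodendrocyte lineage cells at 4365 and 2960 CPM, where it was lower after FLASH by 0.56 (log2 ratio -0.56). Cdkn1a, the cell cycle inhibitor induced by p53, had 37.3 and 50.9 CPM (0.45, 0.35 to 0.54). It leads a small cluster of 12 standard and 42 FLASH cells, and its ratio was 0.27 when clusters were held to the same mix. A Cdkn1a UMI was seen in 11.9% and 13.9% of tumour-lineage cells, and in 4.96% (4.41 to 5.55) and 6.51% (5.94 to 7.11) after thinning to 2000 UMIs, which left out 660 and 713 cells. Median depths were 6128 and 5612 UMIs, and no class that should lack Cdkn1a was at hand. Cirbp, a cold- and stress-induced RNA-binding protein, was higher by 0.29.

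Sox18, known as a transcription factor of the vessel lining, was lower after FLASH in tumour-lineage cells, with 85.4 CPM (82.5 to 88.3) after standard and 55.9 CPM (53.7 to 58.1) after FLASH (log2 ratio -0.61). Cox17, the copper chaperone for cytochrome c oxidase, had 99.0 and 74.3 CPM (-0.41, -0.48 to -0.35). The splicing protein gene Snrpg had 355 and 280 CPM (-0.35), the prohormone convertase gene Pcsk2 had a log2 ratio of -0.37, and the mitochondrial leucyl-tRNA synthetase gene Lars2 of -0.37. Lars2 is also among the leading genes of unnamed clusters of low depth, which were left out of this class. The immediate early gene Junb had 67.1 and 52.9 CPM (-0.34). Olfr1369-ps1 (83.6 and 53.7 CPM, -0.64) and Gfod2 (-0.34) had most of their UMIs in few cells. Hist1h4d, a histone gene with near copies whose reads are uncertain, and Hes1, a target of Notch and SHH signals, had ratios of -0.43 and -0.34, and both lead clusters of progenitor-like cells.

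On mm10, Mbp lies on chromosome 18 from 82475146 to 82585637, Eif4ebp1 on chromosome 8 from 27260329 to 27276674, Mthfd2 on chromosome 6 from 83305691 to 83325908 and Cdkn1a on chromosome 17 from 29090976 to 29100727. Among the genes lower after FLASH, Sox18 lies on chromosome 2 from 181669836 to 181671640, Cox17 on chromosome 16 from 38346991 to 38352763 and Olfr1369-ps1 on chromosome 13 from 21111483 to 21119095.

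**Figure D2:**
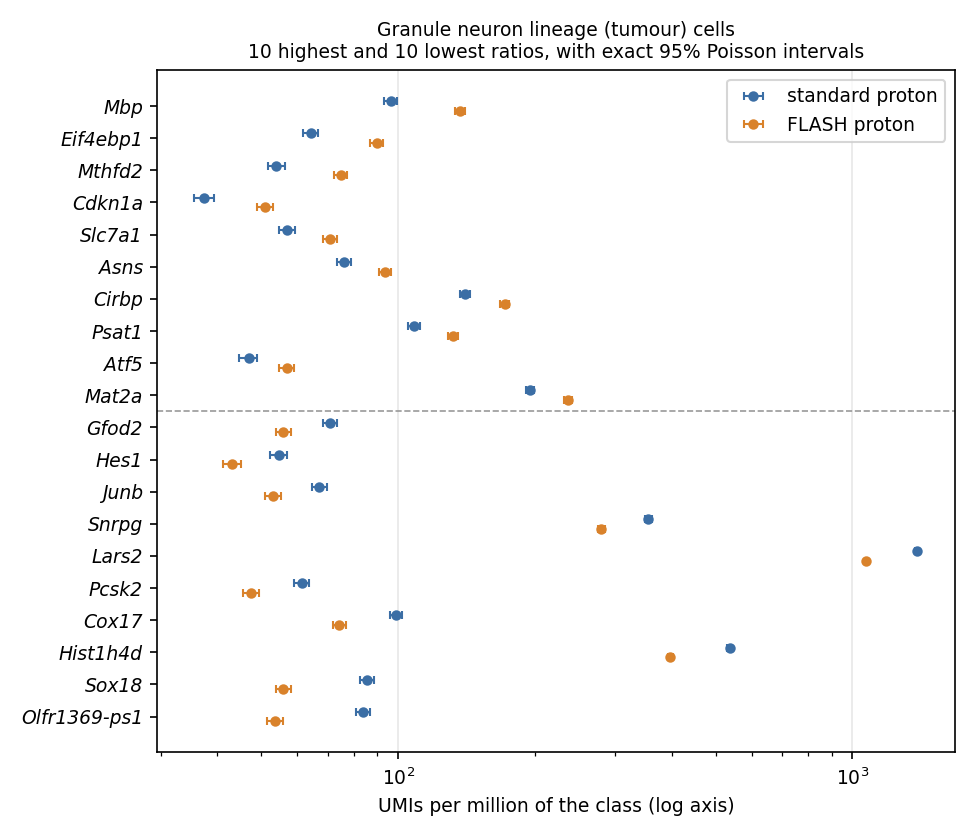
CPM (log axis) of the 10 genes with the highest and the 10 with the lowest FLASH to standard ratio in tumour-lineage cells, as points with exact 95% Poisson intervals. Mbp heads the genes higher after FLASH with 96.3 and 137 CPM, and Olfr1369-ps1 and Sox18 close the lower genes with 83.6 and 53.7 CPM and with 85.4 and 55.9 CPM.

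Genes of DNA replication were slightly higher after FLASH in tumour-lineage cells. Of 42 S phase genes, 37 had a ratio above 0, with a median log2 ratio of 0.11 at percentile 100 of 10000 matched random lists. Ubr7 (0.28), the uracil glycosylase Ung (0.20) and the methylation maintenance factor Uhrf1 (0.19) had the largest ratios. The median was 0.031 when clusters were held to the same mix, so the 0.11 rested largely on the mix of clusters. The matched random lists, taken without that adjustment, ranged from -0.021 to 0.035. Of 52 G2 and M phase genes, 38 lay above 0 with a median of 0.024 (percentile 89.0), with the insulator Ctcf and the kinetochore gene Ndc80 both at 0.14. Of 30 DNA repair genes, 20 lay above 0 with a median of 0.050 (percentile 98.8). Chek1, the checkpoint kinase, had 21.8 and 29.1 CPM (0.41, 0.29 to 0.54), Fanci 0.21, Fancd2 0.20 and Ddb2 -0.19. The 18 SHH targets had a median of 0.065 (percentile 99.6), with 11 above 0, among them the cyclin Ccnd2 (0.15) and the SHH-binding protein Hhip (0.13), while Igf2 (-0.47) and Gli3 (-0.21) lay below. The 25 differentiation genes had a median of -0.023 (percentile 4.74), with Calb2 at 0.37, Meg3 at -0.31 and Neurod1 at -0.18. That median was 0.046 with clusters in the same mix.

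Of 27 p53 targets measured in tumour-lineage cells, 20 lay above 0, with a median log2 ratio of 0.088 (percentile 100). The BH3-only gene Pmaip1 (0.50), the stress sensor Sesn2 (0.48), Cdkn1a (0.45) and the kinase gene Plk2 (0.39) led the list. The median was -0.012 when cells were thinned to 2000 UMIs. The 21 apoptosis genes had a median of -0.026 (percentile 12.1), with Casp9 at 0.28 and Casp8 at -0.19. Of 18 NRF2 and antioxidant genes, 12 lay above 0 with a median of 0.037 (percentile 91.6). The cystine carrier Slc7a11, with 4.69 and 7.71 CPM, was higher by 0.72 (0.46 to 0.98), and haem oxygenase Hmox1 by 0.28. The 11 interferon-stimulated genes had a median of 0.12 (percentile 93.4), with Ifi27l2a at 0.83, Ifi27 at 0.61 and Xaf1 at -0.42. The 8 MHC class I genes had a median of -0.069 (percentile 14.3), with the peptide-loading gene Tapbp at -0.45 and H2-K1 at 0.28, and this median lay between -0.22 and 0.14 over 16 alternatives.

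Immediate early and heat shock genes, which tissue digestion raises, were lower after FLASH in tumour-lineage cells. Of 20 measured, 16 lay below 0, with a median of -0.16 at percentile 0. Besides Junb, the small heat shock gene Hspb1 had -0.48 and Ier3 -0.33, while Hspa1b (-1.36) has the near copy Hspa1a, so its reads are uncertain. The 19 hypoxia and glycolysis genes had a median of -0.032 (percentile 11.2), with Egln3 at 0.37, Vegfa at 0.26 and Bnip3 at -0.26. Free RNA from myeloid cells, read on 11 genes, had a median of 0.031 (percentile 68.6), with Cd74 at -0.54 and Apoe at 0.14. The 4 haemoglobin genes, which have near copies, had a median of 0.33, and of -0.00392 without the 5 cells with most UMIs of each gene in each library.

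**Figure D3:**
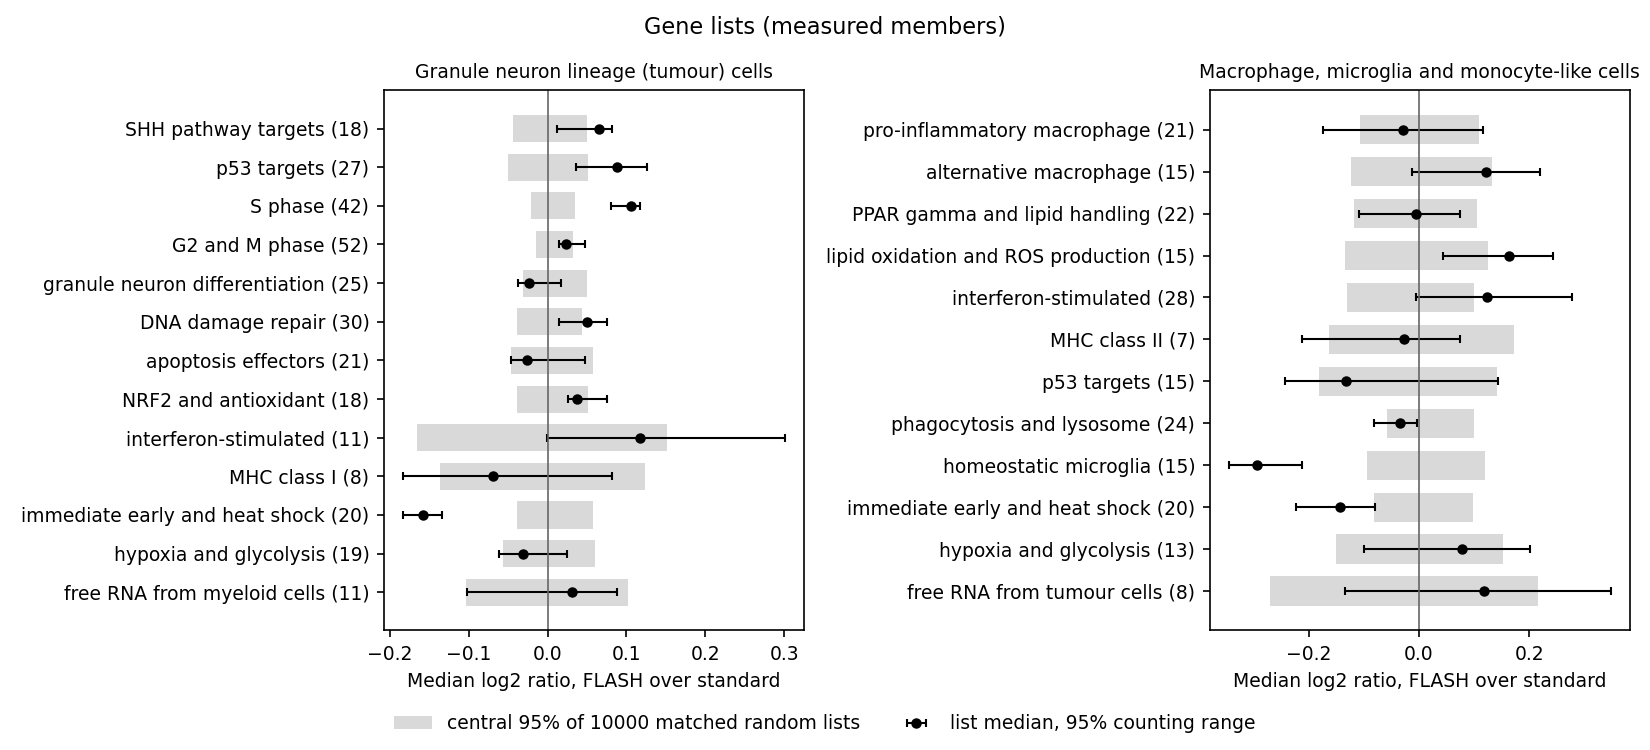
Median log2 ratio (FLASH over standard) of each gene list in tumour-lineage cells and in macrophage-, microglia- and monocyte-like cells, as points with 95% counting ranges over grey bars for the central 95% of 10000 matched random lists, with the number of measured genes in brackets. S phase genes in tumour-lineage cells lie at 0.11, and immediate early and heat shock genes lie below their bars in both panels, at -0.16 and -0.14.

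Progenitor-like cells (3697 standard, 4799 FLASH) made up most of the tumour-lineage sum, so shared leading genes were in part built in. Mbp was at 0.67, Mthfd2 at 0.45 and Eif4ebp1 at 0.43, followed by the condensin gene Ncapg2 (0.35) and the tyrosyl-tRNA synthetase gene Yars (0.34). The lowest were Dqx1 (-0.73, in few cells), Sox18 (-0.60), Olfr1369-ps1 (-0.53), Hist1h4d (-0.47) and Cox17 (-0.45). S phase genes had a median of 0.080 (percentile 100) and p53 targets of 0.072 (percentile 98.8), and these were 0.031 and 0.061 with clusters in the same mix.

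In differentiating granule neuron-like cells (2654 standard, 2919 FLASH), the sums of p53 targets were higher and those of mitotic genes lower after FLASH, and the mix of clusters set the latter. Of 24 p53 targets, 19 lay above 0 with a median of 0.18 (percentile 100), and of 0.097 with clusters in the same mix. Cdkn1a had 16.7 and 39.1 CPM (1.22, 0.98 to 1.48), Plk2 had 3.63 and 7.94 CPM (1.12), and the BH3-only gene Bbc3 had a ratio of 0.32; all 3 lead the small cluster of 12 standard and 42 FLASH cells. Of 51 G2 and M phase genes, 43 lay below 0 with a median of -0.22 (percentile 0), 4 of them by at least 1.5 times, while with clusters in the same mix the median was -0.0046 with 25 above 0 and 26 below. The spindle motor Kif11 had 37.4 and 21.4 CPM, the centromere motor Cenpe -0.62, Hmmr -0.62 and Cenpf -0.52. Mki67, the proliferation marker, had 254 and 164 CPM (-0.63) and leads the nuclear-RNA-rich cluster of 548 standard and 389 FLASH cells. SHH targets had a median of -0.063 and DNA repair genes of -0.073, against 0.019 and -0.035 with clusters in the same mix.

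Meis2 (12.6 and 59.1 CPM, 2.23), Ren1 (27.3 and 89.9 CPM, 1.72) and Mroh2a (0.68) had the highest ratios in differentiating cells, and all 3 lead a cluster of 44 standard and 180 FLASH cells, which is mostly of 1 library. Meis2 is a homeobox gene of hindbrain and other neurons, and Ren1 encodes renin. The cell adhesion gene Opcml (0.42) and the phosphatase subunit gene Ppp2r2b (0.41) came next. Olfr1369-ps1 (-1.31), Sox18 (-0.72) and the long RNA AC160336.1 (-0.54) were among the lowest. The cluster led by Ren1 and Meis2 had 0 granule lineage markers among its 10 leading genes. Cells with at least 2 UMIs of Meis2, Hoxa2 and Hoxb2 together had more of the progenitor marker Atoh1 than other tumour-lineage cells. It had 112 against 65.9 CPM after standard and 81.6 against 61.8 CPM after FLASH. Whether the cells of that cluster are differentiating thus stays open.

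In macrophage-, microglia- and monocyte-like cells (196 standard, 224 FLASH), 97.3% of 2609 genes lay within 1.5 times of each other. Ly6a, which encodes the interferon-inducible surface protein Sca-1, had 16.7 CPM after standard and 69.3 CPM after FLASH, a log2 ratio of 2.03 (1.44 to 2.71). It belongs to a family of near copies, so its reads are uncertain. The T cell-attracting chemokine genes Cxcl10 (23.5 and 80.9 CPM, 1.77) and Ccl5 (24.8 and 93.6 CPM, 1.90) had higher sums after FLASH, with 32.0% and 44.6% of their UMIs in 1 cell. The UMIs of Cxcl10 lay in 11 and 12 cells and those of Ccl5 in 8 and 8. Cxcl10 turned to -0.047 with at least 1000 genes per cell and to -0.0045 with at most 5% mitochondrial UMIs, and Ccl5 had 3 and 5 UMIs outside the 5 cells with most of them in each library. Itgax, which encodes CD11c, had 60.1 and 26.0 CPM (-1.20, -1.75 to -0.68), and the antiviral gene Rsad2 had 63.1 and 28.9 CPM (-1.12). Itgax was at -0.19 with at least 1000 genes per cell, and Rsad2 turned to 0.40 with at most 5% mitochondrial UMIs. The cytokine gene Il1a had 60.1 and 34.1 CPM (-0.81, -1.31 to -0.34).

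Retnla, a marker of alternative activation, had 9.29 and 60.1 CPM in this myeloid class (2.65, 1.91 to 3.58), with 73.1% of its UMIs in 1 cell and all of them in 5 cells of each library. AW112010 (1.79), Slfn1 (1.16) and Crybb1 (0.95) were higher, as was S100a8 (1.45, with 53.2% of UMIs in 1 cell), a neutrophil gene. Over 15 alternatives, AW112010 fell to 0.60, Slfn1 to 0.18 and Crybb1 to 0.23, and S100a8 lay between -5.01 and 2.33. Npnt was at -1.08 and Nol4l at -2.80, the latter with 68.7% of UMIs in 1 cell. Several named genes lead the clusters that define the 3 types: Vcan (1.88) and Plac8 (1.03) for monocyte-like cells, Adamts1 (-0.86) and Ecscr for microglia-like cells, and Igfbp4 (-1.08), Ccl7 and Acp5 (-0.79) for macrophage-like cells. Vcan and Plac8 turned to -2.35 and -3.24 when each library was clustered by itself. Retnla is among the 10 leading genes of the dendritic cell-like cluster, and AW112010 among those of the T cell-like cluster. Ccl5 had 839 and 1399 CPM in T cell-like cells. The border between clusters can thus set the myeloid ratios of Retnla, AW112010 and Ccl5 too. Ccl7 had 133 and 70.5 CPM, and Ecscr had 71.8 and 42.7 CPM.

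On mm10, Ly6a lies on chromosome 15 from 74994877 to 74998031, Cxcl10 on chromosome 5 from 92346638 to 92348889, Ccl5 on chromosome 11 from 83525778 to 83530518 and Retnla on chromosome 16 from 48842551 to 48844461. Itgax lies on chromosome 7 from 128129547 to 128150657 and Rsad2 on chromosome 12 from 26442746 to 26456452.

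**Figure D4:**
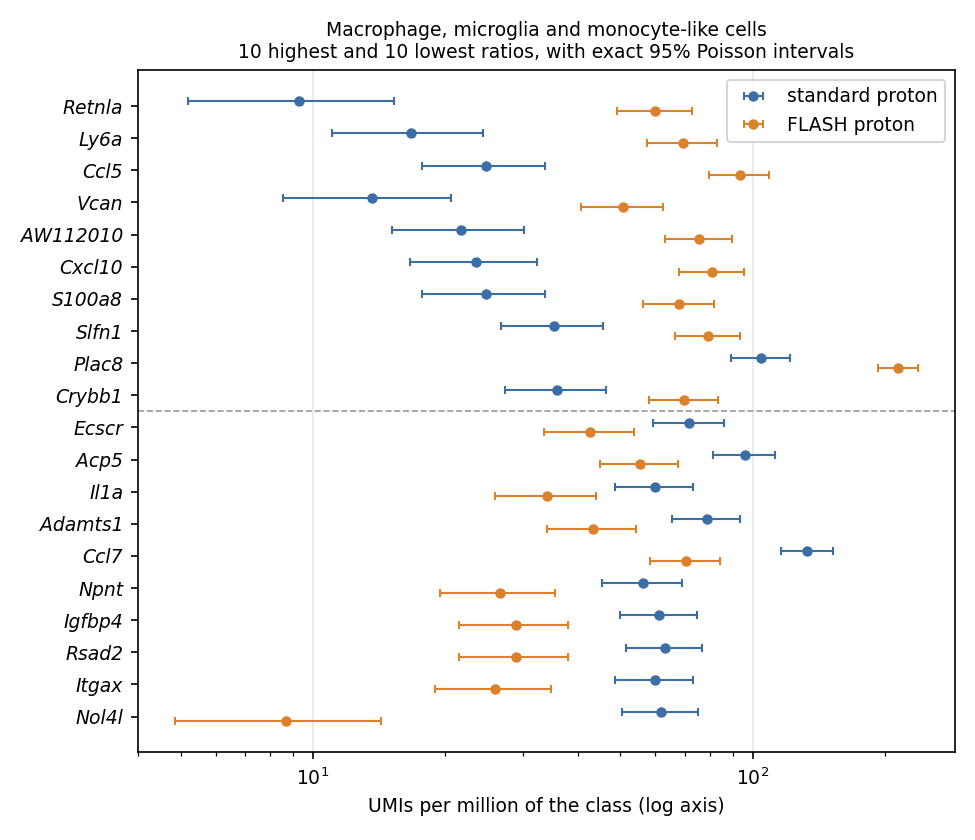
CPM (log axis) of the 10 genes with the highest and the 10 with the lowest FLASH to standard ratio in macrophage-, microglia- and monocyte-like cells, as points with exact 95% Poisson intervals. Retnla and Nol4l mark the ends with log2 ratios of 2.65 and -2.80, and 73.1% and 68.7% of their UMIs lay in 1 cell.

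Neither inflammatory nor alternative activation genes moved one way as a group in the myeloid class. Of 21 pro-inflammatory genes, 3 were at least 1.5 times higher and 3 lower, with a median of -0.029 (percentile 30.6). Besides Cxcl10, Ccl5 and Il1a, Cxcl9 had a ratio of 2.98 with 80.4% of its UMIs in 1 cell. Of 15 alternative activation genes, 2 were higher and 2 lower by that size, with a median of 0.12 (percentile 96.6). The mannose receptor Mrc1 had 249 and 155 CPM (-0.68, -0.91 to -0.45), Mmp12 -1.19 and the monocyte cluster gene Chil3 0.95. The 28 interferon-stimulated genes had a median of 0.12 (percentile 99.2), with tetherin Bst2 at 541 and 839 CPM (0.63, 0.51 to 0.76) and the RNA sensor Ifih1 at -0.68. This median turned to -0.22 in macrophage-like cells by themselves and was 0.77 with at most 5% mitochondrial UMIs.

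PPAR gamma and lipid handling genes, 22 in number, showed no shift in the myeloid class, with a median of -0.0051 (percentile 45.0) and 0 members past 1.5 times. The partner receptor Rxra had 44.6 and 31.8 CPM, and the fatty acid oxidation genes Acadl and Acadm had ratios of -0.47 and -0.30. Pparg itself had 14 and 15 UMIs (8.67 CPM in both), and the fatty acid carrier Cd36 had 48.9 and 50.3 CPM (0.038, -0.42 to 0.50). A Pparg UMI was found in 6.63% and 5.80% of these cells, and after thinning in 3.11% (1.15 to 6.64) and 1.83% (0.502 to 4.63), with 3 and 6 cells left out. In tumour-lineage cells, which should lack Pparg, the thinned shares were 0.0527% and 0.0143%. Median depths were 7638 and 7241 UMIs in the myeloid class and 6128 and 5612 in tumour-lineage cells. Any difference in Pparg was not detectable at this depth.

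Lipid oxidation and ROS production genes were slightly higher after FLASH in the myeloid class. Of 15 measured, 9 lay above 0, with a median of 0.16 (percentile 99.4) and 0 past 1.5 times. Alox5ap, which presents arachidonic acid to 5-lipoxygenase, had 184 and 267 CPM (0.54, 0.32 to 0.75), the leukotriene hydroxylase Cyp4f18 0.46 and the NADPH oxidase subunit Ncf4 0.34, while the cyclooxygenase Ptgs1 lay at -0.44. The median was -0.051 when each library was clustered by itself. Alox5 had 4 UMIs in each library, and Alox15 and Nos2 had 0, where the floor of 3 counts is 1.86 and 1.73 CPM. Of the cholesterol synthesis genes 2 were measured, Hmgcs1 (0.57) and Insig1 (0.35), with a median of 0.46 (percentile 93.5).

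Homeostatic microglia genes were lower after FLASH in the myeloid class, with 14 of 15 below 0 and a median of -0.29 (percentile 0), for example P2ry12 (-0.72) and Sall1 (-0.58). They are markers of microglia-like cells, which were 29.1% and 18.3% of this class, and in macrophage-like cells alone the median was 0.081. Of 24 phagocytosis and lysosome genes, 17 lay below 0 with a median of -0.034 (percentile 6.47), with the protease Ctsl at -0.61, the receptor Axl at -0.55 and its ligand Gas6 at 0.61. The median was 0.0095 with the clusters of the class in the same mix. The 7 MHC class II genes had a median of -0.027 (percentile 30.3), with H2-Eb1 at -0.35, and it lay between -1.02 and 0.88 over 17 alternatives. The 15 p53 targets, with Bbc3 at -0.69, had a median of -0.13 (percentile 9.61), which turned to 0.19 with cells thinned to 2000 UMIs and to 0.17 without the 5 top cells. Immediate early and heat shock genes had a median of -0.14 (percentile 0.05), with the co-chaperone Dnajb1 at -0.55 and the near-copy pair Hspa1a (-0.73) and Hspa1b (-1.39). The 13 hypoxia and glycolysis genes had a median of 0.078 (percentile 83.4), with hexokinase Hk2 at -0.56 and enolase Eno1 at 0.46. Free RNA from tumour cells, read on 8 genes, had a median of 0.12 (percentile 88.3), with Stmn1 at 0.32, and Hbb-bs, the 1 haemoglobin gene measured, had -0.66.

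In macrophage-like cells alone (117 standard, 137 FLASH), some interferon-stimulated and some alternative activation genes were lower after FLASH. Arginase Arg1 had 123 CPM (103 to 147) after standard and 30.6 CPM (21.5 to 42.2) after FLASH, a log2 ratio of -2.00 (-2.58 to -1.47). A UMI of Arg1 was seen in 18.8% and 10.9% of these cells at median depths of 7830 and 8227 UMIs. After thinning, which left out 1 and 2 cells, the shares were 12.1% (6.76 to 19.4) and 4.44% (1.65 to 9.42), against 0.0527% and 0% in tumour-lineage cells. In the whole myeloid class Arg1 had 144 and 166 CPM, so the difference did not hold across the 3 types together. Arg1 and Ccl24 are among the 10 leading genes of the monocyte-like cluster (22 and 46 cells), so the border between these clusters can set their ratios. Rsad2 had -2.01, Itgax -1.64, Ccl24 150 and 10.8 CPM (-3.75, with 54.8% of UMIs in 1 cell) and Ctsl -1.25 (39.8% in 1 cell). Ly6a (2.81), Retnla (2.61), AW112010 (1.90), Ccl5 (1.77) and the phospholipase gene Pla2g16 (1.14) had the highest ratios.

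Of 26 interferon-stimulated genes in macrophage-like cells, 17 lay below 0 and 9 above, with a median of -0.22 (counting range -0.33 to 0.041, percentile 0.11). By at least 1.5 times, 5 were lower, among them Ifit2 at -1.13 and Ifih1 at -0.86, and 3 were higher, namely Cxcl10 (0.82), Ifi27l2a (0.79) and Bst2 (0.59). Of 15 alternative activation genes, 6 were at least 1.5 times lower and 2 higher, with a median of -0.0063. Lipid oxidation and ROS production genes had a median of 0.22 (percentile 100), with leukotriene C4 synthase Ltc4s at 0.62, and the 9 hypoxia and glycolysis genes of 0.26 (percentile 99.9), with Eno1 at 0.68 and Aldoa at 0.41. Medians lay at 0.053 for pro-inflammatory genes, where Ccl2 had -1.02, at -0.028 for PPAR gamma and lipid handling, 0.0031 for phagocytosis, 0.095 for p53 targets, -0.019 for immediate early and heat shock genes and -0.019 for MHC class II.

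Oligodendrocyte lineage cells (120 standard, 167 FLASH) had higher levels of the immediate early genes Ier2 and Egr1 after FLASH, while most genes of that list were lower in tumour-lineage cells. Ier2 had 100 and 211 CPM (1.07, 0.70 to 1.45), Egr1 had 176 and 354 CPM (1.01, 0.73 to 1.30) and Junb 0.50, within a list of 13 whose median was 0.098 (percentile 86.1). Apoe, the lipid carrier, had 1946 and 558 CPM (-1.80, and -0.91 as the mean over cells), and Ptgds, which makes prostaglandin D2 and leads the mature oligodendrocyte cluster, had -2.21 with 31.0% of its UMIs in 1 cell. The potassium channel gene Kcnd2 (1.46) and Ly6h (1.30) were higher. The 11 hypoxia and glycolysis genes had a median of 0.013, with Ndrg1 at -0.92.

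Single cells held a large part of the UMIs of several genes in oligodendrocyte lineage cells. Pcp4, a Purkinje cell gene, had 7.17 and 135 CPM with 62.9% of UMIs in 1 cell and only 6 UMIs in the standard library. Gfod2 (2.82), the histone gene with near copies Hist1h1b (1.83), Zc3h7b (-1.92) and Cenpf (-1.81) also had 33.0% to 58.6% of UMIs in 1 cell. Without the 5 cells with most UMIs in each library, Hist1h1b was at 0.77, while Zc3h7b turned to 0.21 and Cenpf to 0.11. The haemoglobin list had a median of 5.74, and of 0.84 without those cells, and 1 cell held 98.0% of the Hbb-bs UMIs.

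The transgene SmoM2EYFP had 22.0 and 25.9 CPM (0.24, 0.11 to 0.36) in tumour-lineage cells, 15.5 and 11.8 CPM (13 and 12 UMIs) in oligodendrocyte lineage cells and 0 and 1 UMIs in the myeloid class, so it did not single out the tumour lineage. Cre, driven by the Math1 enhancer, had 843 and 724 CPM (-0.22) in tumour-lineage cells, 87.3 and 118 CPM in oligodendrocyte lineage cells and 20.4 and 23.7 CPM in the myeloid class.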

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

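The lists of amino acid response genes and the comparison of the subclasses were chosen only after their first values were seen, as was the test of the same members in 2 classes, while the outcome of each other test below on these genes was not known when it was written down.

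Amino acid response genes, which ATF4 switches on when amino acids run short or translation is stressed, were higher after FLASH in tumour-lineage cells. The 11 genes first noticed, among them Eif4ebp1, Mthfd2, Asns, Psat1, Sesn2 and Slc7a11, had a median log2 ratio of 0.31, and 27 further members not looked at before had a median of 0.20, above the range of -0.033 to 0.044 of matched random lists, with 24 of them above 0 (Trib3 0.95, Chac1 0.45, Gpt2 0.42, Atf4 itself 0.11 and Ddit3 -0.022). For the genes first seen, another mix of tumour clusters in the 2 libraries is argued against. They kept a median of 0.29 when every cluster weighed the same in both. The shift was uneven, with medians of 0.31 in the largest progenitor-like cluster and 0.64 in the nuclear-RNA-rich cluster. In the largest differentiating cluster their median was 0.14, inside the random range of -0.15 to 0.16. In the next largest it was 0.023, inside the range of -0.20 to 0.19. The further members were not put to the check with equal weights. Within single clusters their median ran from 0.013 to 0.35. In the largest progenitor-like cluster it was 0.13, and in the largest differentiating cluster 0.072, inside the random range of -0.074 to 0.077. For them, the mix as a part of the 0.20 stays open. A stress of the whole suspension stays open, since all members had a median of 0.042 in macrophage-, microglia- and monocyte-like cells, inside the random range of -0.14 to 0.099, and of -0.037 in oligodendrocyte lineage cells, and these classes hold too few counts to exclude it, with a myeloid counting range that reaches 0.17 where the same members had 0.17 to 0.22 in tumour-lineage cells. A stronger amino acid response of tumour cells after FLASH may account for the pattern, as may a difference between the 2 tumours that has nothing to do with the dose rate, and 1 library per group cannot separate them.

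In the unnamed tumour-like clusters of low depth, left out of the comparisons, the amino acid response genes first seen had a median log2 ratio of 0.19 (counting range 0.012 to 0.32). The 21 further members measured there had -0.040 (-0.11 to 0.11), inside the range of -0.13 to 0.095 of matched random lists. No difference of these further members was thus seen there.

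The G2 and M phase genes had a median log2 ratio of -0.22 in differentiating cells and of 0.026 in progenitor-like cells, the latter inside the range of -0.010 to 0.040 of matched random lists, a difference of 0.25. With clusters in the same mix the medians were -0.0046 and 0.0070, so the difference rested on the mix of clusters.

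DNA damage repair genes had medians of 0.051 in progenitor-like and -0.073 in differentiating cells, both inside the ranges of matched random lists, a difference of 0.12. With clusters in the same mix the medians were 0.033 and -0.035.

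Barcodes left out for their mitochondrial share held 107 Cdkn1a UMIs, with 43 in 1587 standard barcodes (15.4 CPM, 11.2 to 20.8) and 64 in 1551 FLASH barcodes (24.7 CPM, 19.0 to 31.6).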

How the results depend on the processing

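Holding the clusters of a class to the same mix, leaving out the 5 top cells of each gene in each library, leaving the leukocyte clusters unsplit and leaving out the nuclear-RNA-rich cluster were chosen after seeing the data. No paired analysis was possible because each group has 1 library and the labels give no shared replicate numbers. The 20 named tumour-lineage genes kept their direction in all 300 values over 15 settings, with Sox18 between -0.65 and -0.59, Eif4ebp1 between 0.39 and 0.54, and Cdkn1a between 0.26 and 0.78. The named myeloid genes kept it in 290 of 298 values, the oligodendrocyte lineage genes in 136 of 138, the gene lists in 441 of 499 and the class shares in 131 of 146. The oligodendrocyte lineage genes had no values under the limit of 5% mitochondrial UMIs, which left 42 standard and 38 FLASH cells of that class. The myeloid and oligodendrocyte lineage values rest on fewer counts, with 1615209 and 836630 UMIs in the standard library against 39908883 in tumour-lineage cells. Beyond counting error, 68 gene list values moved and 9 turned, as 14 and 2 class shares did. Myeloid MHC class II ranged from -1.02 to 0.88, myeloid p53 targets from -0.22 to 0.19, tumour-lineage MHC class I from -0.22 to 0.14 and the progenitor-like share from 0.022 to 0.22. A part of the other log2 ratios that moved or turned is given by setting. With at least 1000 genes per cell, the myeloid share was -0.39, S phase 0.077, tumour-lineage haemoglobin -0.074, myeloid pro-inflammatory genes -0.19, alternative genes 0.30, interferon genes 0.70, Cxcl10 -0.047 and S100a8 -1.23. With at least 200 genes, the differentiating share was 0.093, the tumour-lineage share 0.065 and S phase 0.064. With at most 20% mitochondrial UMIs, S phase was 0.067. With at most 5%, SHH targets were at 0.090, differentiation at 0.021, pro-inflammatory genes at -0.21, lipid oxidation at 0.038, myeloid interferon genes at 0.77, Cxcl10 at -0.0045 and Rsad2 at 0.40. At 1000 genes and at 5%, 70.0% and 66.7% of the myeloid cells kept their name. At resolution 0.5, S100a8 was -0.84. With each library clustered by itself, the microglia-like share was 0.47, tumour-lineage p53 targets 0.013, pro-inflammatory genes -0.33, alternative genes -0.062, lipid oxidation -0.051, myeloid interferon genes -0.043, phagocytosis 0.00683, Vcan -2.35, S100a8 -5.01 and Plac8 -3.24. With cells thinned to 2000 UMIs, tumour-lineage p53 targets were at -0.012, lipid oxidation at 0.25 and myeloid interferon genes at 0.40, and free RNA from tumour cells in the myeloid class at 0.67. With the same mix, S phase was 0.031, differentiation 0.046, myeloid interferon genes -0.067 and phagocytosis 0.0095. With the mean over cells, lipid oxidation was 0.26 and myeloid interferon genes 0.28. With list members of at least 10 UMIs, myeloid haemoglobin was 0.46, and with at least 200 UMIs myeloid interferon genes were at 0.33. In macrophage-like cells by themselves, interferon genes were at -0.22, phagocytosis at 0.0031 and homeostatic microglia genes at 0.081. Without the 5 top cells, tumour-lineage haemoglobin was -0.00392, alternative genes 0.29, myeloid interferon genes 0.41, Zc3h7b 0.21 and Cenpf 0.11. The causes were not tested.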

Other observations

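The genes in the first 2 paragraphs were chosen after their values were seen, and the test of Hox transcripts against free RNA was written after the result was seen, in place of an earlier form whose outcome was fixed by its design. The minimum of 10 UMIs left, used in the last paragraph, was also set after the result was seen. The classes in the next paragraph hold under 50 cells in at least 1 library, and their values carry counting error only.

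In microglia-like cells (57 standard, 41 FLASH) Spp1, the osteopontin gene of activated microglia, had 2585 and 10880 CPM (log2 ratio 2.07, 1.98 to 2.17), with 24.8% of its UMIs in 1 cell, but Spp1 is a leading gene of a macrophage-like cluster and had 8086 and 5303 CPM (-0.61) in macrophage-like cells, so the border between clusters can set this ratio, while the homeostatic gene P2ry12 had 639 and 441 CPM (-0.53). In monocyte-like cells (22 and 46) the matrix protein gene Thbs1 was higher after FLASH by 1.34 (0.91 to 1.82) and Arg1 by 0.55 (0.22 to 0.90), the other direction from Arg1 in macrophage-like cells, while Spp1 had -1.64. In T cell-like cells (20 and 24) Ifng, the interferon gamma gene, had 20 and 5 UMIs (32.0% in 1 cell), and the granzyme gene Gzmb had 13 and 38 UMIs (47.1% in 1 cell). In endothelial-like cells (33 and 50) the tight junction gene Cldn5 was higher by 0.52 (0.38 to 0.65). Cldn5 is a marker by which this cluster was named and leads it, so the border of the cluster can set this ratio.

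Some transcripts sat in few tumour-lineage cells of both libraries. Of 7584 genes with at least 1000 UMIs, the median gene had 11.1% of its UMIs in the 141 cells richest in it, and 9 genes had over 50%, among them Dqx1 (90.8%), Gfod2 (71.7%), Olfr1369-ps1 (69.9%) and Nol4l (67.0%). Skeletal muscle genes such as Mylpf and Tnnc2 had 1802 and 423 UMIs in tumour-lineage cells, and 1 cell of each library held 88.5% and 36.6% of them.

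Tumour-lineage cells with at least 2 UMIs of Meis2, Hoxa2 and Hoxb2 together numbered 47 in the standard library (0.740% of tumour-lineage cells, 0.544 to 0.983) and 185 in the FLASH library (2.40%, 2.07 to 2.76). Hoxa2 and Hoxb2 mark the hindbrain behind the cerebellum, while Meis2 is a gene of other neurons too. Since 2 UMIs of Meis2 alone were enough, this is not a count of cells with Hox transcripts. Meis2 had 194 and 984 UMIs in tumour-lineage cells, and all Hox2 to Hox5 genes 146 and 208. The level of Hox2 to Hox5 genes over all tumour-lineage cells was 3.66 CPM (3.09 to 4.30) and 4.58 CPM (3.98 to 5.25), and that of Hox3 to Hox5 genes 0.977 CPM and 0.837 CPM. Free RNA is argued against, since 61.1% of the 208 UMIs of Hox2 to Hox5 genes in FLASH tumour-lineage cells lay in cells with at least 2 of them, where UMIs spread by depth gave 0.962% to 6.73%. A candidate explanation of these cells, though not of their number, is tumour cells from the hindbrain behind the cerebellum within the dissected tissue, since their En1 and En2 level, which marks the cerebellum, was 0.189 times (0.114 to 0.296) that of the other tumour-lineage cells, and their Hox3 to Hox5 level was 66.8 CPM against 0.354 CPM in the standard and 13.4 CPM against 0.410 CPM in the FLASH library. After thinning to 2000 UMIs (660 and 713 cells left out), Meis2 was found in 0.474% and 2.24% of tumour-lineage cells (0.882% and 3.43% unthinned) and Hoxa2 in 0.105% and 0.485% (0.268% and 1.14%), while Hoxb2 went the other way with 0.299% and 0.143% (0.646% and 0.492%). Thinned myeloid cells had Meis2 in 0.518% and 0% (median depths 6128, 5612, 7638 and 7241 UMIs), and with 1 tumour preparation per group the site of origin cannot be told apart from the irradiation.

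The largest ratios in macrophage-, microglia- and monocyte-like cells rest on small classes, so few cells or another mix of the 3 types could account for them. Without the 5 cells with most UMIs of each gene in each library, 17 of the 18 named genes with at least 10 UMIs left kept a difference of at least 1.5 times in the same direction, Acp5 did not, and Retnla had 0 and 0 UMIs left and Ccl5 3 and 5, so few cells stay open for them. With the clusters of these 3 types in the same mix, 16 of the 20 kept it, and Plac8, Adamts1, Il1a and Ecscr did not. Keeping 1.5 times does not mean keeping the full ratio, and the top cells were taken from both libraries. For S100a8 and Nol4l a single cell held most of the UMIs, so few cells stay open for them too. All UMIs of Cxcl10 lay in 11 standard and 12 FLASH cells, so leaving out 5 per library cannot decide this, and few cells stay open for Cxcl10 as well. For the other genes that kept the difference, these values argue against few cells as the whole cause. For the genes that kept the difference in the same mix, they argue against the mix as the whole cause. Fewer kept it under other choices of cells, with 12 of the 20 under the limit of 5% mitochondrial UMIs, 13 with at least 1000 genes and 15 with each library clustered by itself, so this choice stays open, and a difference in activation after FLASH and a difference between the tumours sampled stay open as untested.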
